A study of Brassica rapa subsp. pekinensis with 6 samples.

How the data were processed

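RNA from developing flower buds of Chinese cabbage was sequenced in 6 libraries, 3 from a male sterile mutant called msm and 3 from its wild type, the line FT. Libraries were assigned to the groups by their titles, and they carry the numbers of those titles (wild type 1, 2 and 4; msm 1, 2 and 3). The labels describe total RNA taken with Trizol and standard Illumina libraries. They do not say whether the libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

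The authors deposited 1 table per library. Per the file headers, each holds for every gene the count of uniquely assigned reads, the gene length, the covered part of that length and an RPKM value. The count column is not normalized: in each library its sum equalled the total that the authors wrote in the header. The RPKM values of the authors are reads scaled to that length and to that total, and they followed from the counts to within a relative difference of 6.4e-15. Every length is a multiple of 3, so it is a coding length. Coverage is deposited as a percentage, and 14 values passed 100, so it was used only to compare libraries. The submitters' processing notes name DESeq, without a version or a role. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and neither is the use of strand. Reads of near-identical gene copies, overlapping genes or antisense genes could therefore have been lost or placed on the wrong gene, and Brassica rapa carries many such copies.

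The tables list genes with at least 1 read, and a gene with no row in a library was taken to have 0 reads there. This gave 35421 genes. The totals were 25402146, 25077713 and 24990396 reads in the wild-type libraries 1, 2 and 4, and 25426200, 26181696 and 24996285 in the msm libraries 1, 2 and 3. A count of 0 in a library allows up to 3 counts, or 0.115 to 0.12 RPM (reads scaled to the library total). Such limits and all counting intervals cover counting error only.

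The gene identifiers were matched to a RefSeq gene table (assembly CAAS_Brap_v3.01) on every identifier and synonym column. A single identifier of the 35421 matched, Bra000116, which the table lists as SWEET9. The groups, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The 18 gene lists, among them the tapetum, sporopollenin and exine, the pollen coat, meiosis, floral organ identity, jasmonate, sugar transport, photosynthesis and stress, could therefore not be tested, because each needed 3 measured members. Protein motif families and chromosome positions were not analysed here, since no genome was used. SWEET9 is named because it was the only gene with a name. For genes without names the rule allows 2 rising and 2 falling identifiers: those with the largest fitted change among called genes whose groups did not overlap and whose mean in the higher group was at least 10 RPKM.

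The groups were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM scaling, the default expression filter and robust fitting. Fold changes are msm over wild type. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold. Where a group had no read of a gene, the fold was bounded by 3 counts per library, with TMM scaling. Alternatives were DESeq2 1.42.0 (which in some fits replaced its parametric dispersion trend by a local regression), limma 3.58.1 on log2(RPKM + pseudocount), other scalings, filters and thresholds, each library left out in turn, and the replicate number as a block. Group means of single measures were compared with exact two-sided permutation tests (SciPy 1.17.1), for which the 20 assignments of 6 libraries give no p below 0.1.

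The fits were tested on simulated data drawn from the means, library sizes and dispersions of the msm and wild-type comparison. Over 28799 genes edgeR recovered 96 of 100 genes changed 3-fold and 98 of 100 changed 8-fold, with 1 false call. DESeq2 recovered 93 and 97 with no false call, and limma, over 26718 genes, 86 and 93 with no false call. Only these few genes were changed, as many raised as lowered, whereas in the real comparison many genes changed and lower ones prevailed. False calls from scaling under such a one-sided change could therefore not appear in the simulation. Libraries of a group differed by more than counting noise, so none was treated as a library deposited again, though repeat preparations of one RNA would differ so too: the chi-square per degree of freedom between 2 libraries of a group was 3.02 to 8.62 over genes with at least 20 reads.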

Results

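The data were read counts per gene from flower buds of Chinese cabbage (Brassica rapa subsp. pekinensis), a leafy vegetable grown for its heads. Buds of plants at full bloom were taken from a male sterile mutant, msm, whose flowers do not give functional pollen, and from its wild type FT. Each group held 3 libraries, with a mean of 25156752 ± 216956 uniquely assigned reads per library in wild type and 25534727 ± 600111 in msm (SD, n = 3 each). Between 32168 and 32213 genes had a read in the msm libraries, against 32837 to 32853 in the wild-type libraries. The libraries of a group lay close together, with a lowest Spearman correlation across genes of 0.993 within groups, against 0.905 to 0.91 between them; genes are not independent replicates. The groups separated on the first axis of a multidimensional scaling at default settings. Its distances use only the genes with the largest log2 fold changes between each pair of libraries. The first axis held 96.2% of the variation in these distances, not of that over all genes, and the second axis held 1.02%. The biological coefficient of variation was 6.49%.

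The comparison of msm with wild type asks which genes differ in expression in the buds of the male sterile plants. Among changes of at least 2-fold, lower genes prevailed. Of the 29104 genes tested, 3641 (12.5%) fell in msm and 1351 (4.64%) rose, by at least 2-fold and at an adjusted p below 0.05 in edgeR's quasi-likelihood test, which is 2.7 genes lower for each gene higher. With no fold threshold 8764 genes were lower and 7802 higher, so that 52.9% were lower. Among called genes the falls were larger than the rises. The median log2 fold change was 1.56 among genes that rose and -2.81 among genes that fell, with genes unread in a group set at their bound (-2.85 as fitted). With scaling by total counts in place of TMM, the median change of all tested genes moved from 0.005 to 0.22 on the log2 scale and 3203 genes were lower and 2030 higher, so that 61.2% of the called genes were lower and not 72.9%.

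The imbalance grew with the size of the change. Genes unread in a group were placed at the bound that 3 counts per library allow, which limits how far weakly expressed genes reach. Among called genes that changed less than 4-fold, 1318 were lower and 896 were higher in msm. At 8-fold or more there were 1710 lower and 205 higher, at 32-fold or more 974 and 54, and at 256-fold or more 338 and 3. As fitted, without these bounds, the numbers were 1752 and 231, 1144 and 104, and 610 and 25. No read of 384 of the lower genes was found in any msm library, and no read of 56 of the higher genes in any wild-type library.

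**Figure D1:**
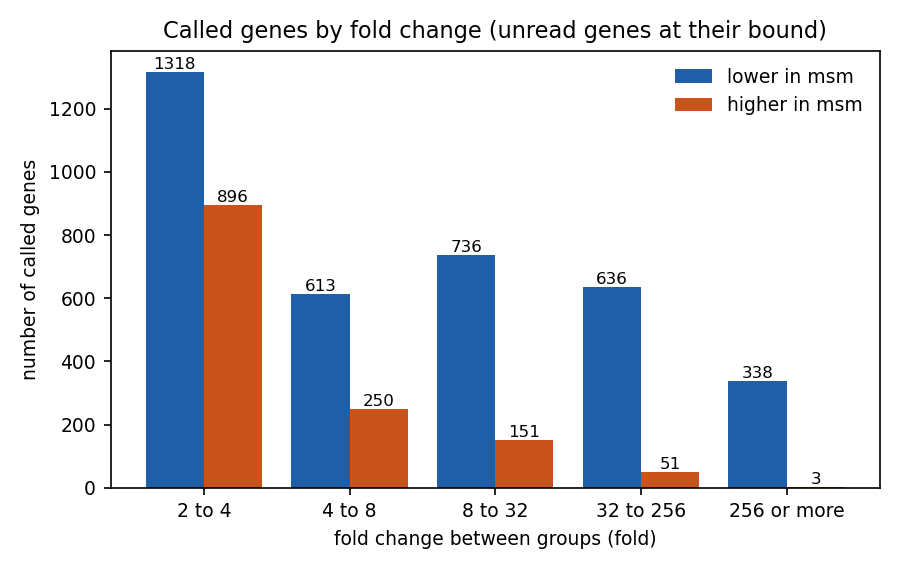
Number of called genes (vertical axis) in classes of fold change between the groups (horizontal axis), blue for genes lower and orange for genes higher in msm, with genes unread in 1 group placed at their lower bound. The class of 256-fold or more holds 338 lower and 3 higher genes, and the class of 2 to 4-fold holds 1318 and 896.

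SWEET9 (Bra000116), a sugar transporter known from nectaries, was the only gene that could be identified by name, and it rose in msm. It had 54, 63 and 57 reads in the msm libraries and none in the wild-type libraries. Its level was 2.79 ± 0.174 RPKM (SD, n = 3) in msm. In wild type a count of 0 allows up to 0.146 RPKM in a library, so that SWEET9 was at least 16.4-fold higher in msm with TMM scaling, as for all bounds given here (adjusted p = 3.3e-11, edgeR). With a pseudocount of 5 RPKM, limma no longer called it, at a log2 difference of 0.64.

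The 4 genes named by the rule, which ranks by fitted change, were unread in 1 of the groups. Such a ranking favours unread genes, whose fitted folds have no firm limit, so these 4 need not have the largest changes. Bra000438, with reads in both groups, fell from a mean of 790.9 RPKM to 0.367 RPKM, at a fitted log2 fold change of -11.29. With unread genes at their bound, 3 other genes were at least 256-fold higher in msm. Bra030208 (coding length 915 bases) rose from no read in wild type to 11.3 ± 0.445 RPKM in msm (SD, n = 3), at least 74.3-fold higher, with an adjusted p of 8.98e-19 in edgeR. Bra028631 (939 bases) rose from no read to 10.2 ± 1.54 RPKM (SD, n = 3), at least 69.02-fold higher, with an adjusted p of 1.05e-17 in edgeR. Bra030122 (516 bases) had 249 ± 11.5 RPKM in wild type (SD, n = 3) and no read in msm, at least 1271-fold lower, with an adjusted p of 8.01e-30 in edgeR. Bra024148 (405 bases) had 213 ± 10.1 RPKM in wild type (SD, n = 3) and no read in msm, at least 854-fold lower, with an adjusted p of 8.76e-29 in edgeR. What these 4 genes encode was not identified here.

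**Figure D2:**
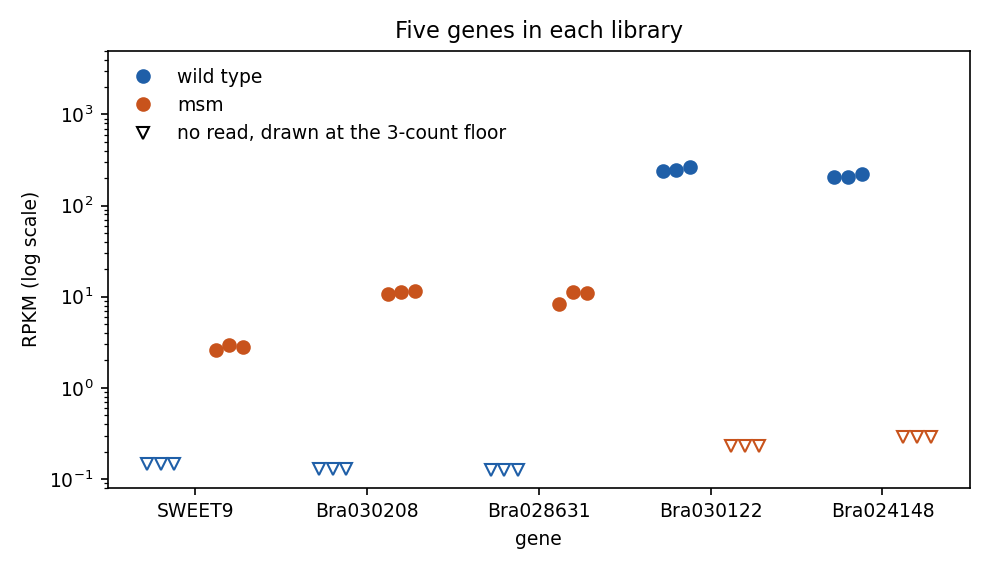
RPKM on a log scale (vertical axis) of SWEET9 and of the 4 genes with the largest fitted changes (horizontal axis), with 1 point per library, blue for wild type and orange for msm. Open triangles are libraries without a read, drawn at the level of 3 counts: SWEET9 reached 2.79 RPKM in msm, and Bra030122 reached 249 RPKM in wild type.

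Genes that were on in one group and off in the other were mostly genes of the wild type. A set of 553 genes had at least 1 RPKM in every wild-type library and less than 0.1 RPKM in every msm library. The reverse held for 47 genes, SWEET9 among them. None of the other 9 splits of the 6 libraries into 3 and 3 gave such a gene. Each of those splits mixes wild-type and msm libraries on both sides, so a gene that follows the groups could not pass there. Their result shows only that no gene divided the libraries of both groups at once in this way. It does not test the counts of 553 and 47. These counts depend on the threshold: at 5 RPKM or more they were 287 and 10, and with no read at all allowed in the other group 315 and 34. The wild-type set was also the more strongly expressed: its median level was 6.09 RPKM in wild type, 210 of its genes reached 10 RPKM and 21 reached 100 RPKM. Among the 47 genes of the msm set the median level was 2.43 RPKM, 7 reached 10 RPKM and none reached 100 RPKM. The median coding length was 1053 bases in the wild-type set and 777 bases in the msm set. In short genes, 0.1 RPKM lies below what 0 reads can exclude: for SWEET9 (813 bases) 0 reads allow up to 0.146 RPKM in a library. Off therefore means few or no reads, not a level shown to be under 0.1 RPKM.

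Genes called lower in msm took a larger share of the reads in wild type than genes called higher took in msm. The 3641 lower genes took 19.5% ± 0.244 of the reads in wild type and 3.54% ± 0.0339 in msm (SD, n = 3 each). The 974 of them at least 32-fold lower took 7.47% ± 0.0233 and 0.0261% ± 0.00146. The 1351 higher genes took 0.893% ± 0.0115 in wild type and 3.15% ± 0.0648 in msm. These genes were chosen on the same libraries, so a check was added after the data were seen. When genes were called from 4 libraries and measured in the other two, over all 9 ways to leave out a library of each group, the lower genes took 19.2% to 19.7% of the wild-type reads and 3.47% to 3.67% of the msm reads. The higher genes took 0.786% to 0.918% and 2.91% to 3.15%.

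**Figure D3:**
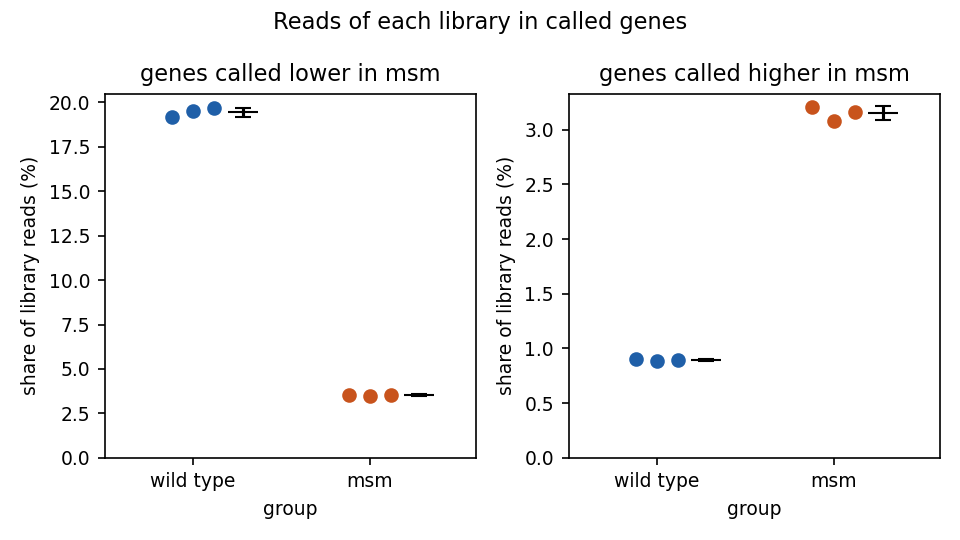
Share of each library's reads in percent (vertical axes) that fell in genes called lower (left) or higher (right) in msm, by group (horizontal axes). Points are libraries and bars are the mean ± SD of 3: the lower genes took 19.5% of the reads in wild type and 3.54% in msm.

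Many of the most abundant genes of the wild type were called lower in msm. Of the 100 genes with the highest mean RPKM in wild type, 55 fell in msm, none rose and 45 were not called. Of the 100 highest in msm, 4 were higher in msm than in wild type, 11 were lower and 85 were not called. The 2 lists shared 52 genes, each was ranked on values that also enter the calls, and the difference between them was not tested. Of the 10 most abundant genes of wild type 7 fell, and of the 10 most abundant of msm none was called.

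Reads were concentrated in fewer genes in wild type. The 100 most abundant genes took 12.4% ± 0.0694 of the reads in wild type and 8.61% ± 0.103 in msm (SD, n = 3 each). All 3 wild-type libraries lay above all 3 msm libraries (exact two-sided permutation p = 0.1, the smallest these libraries allow). More genes were detected in wild type, at 1 RPKM or more and with at least 10 reads: 26418 ± 27.2 against 25476 ± 61.7 in msm (SD, n = 3 each), again without overlap (exact permutation p = 0.1). At 5 RPKM the numbers were 19653 ± 52.7 and 19572 ± 52 (SD, n = 3 each) and the groups overlapped (exact permutation p = 0.2). RPKM is scaled to total reads, whereas the TMM factors were 0.925 to 0.929 in wild type and 1.07 to 1.08 in msm. On the TMM scale a fixed RPKM minimum is therefore stricter in wild type. Detected genes were not counted on that scale, so both differences may depend on scaling.

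Called genes were found in all classes of abundance and of gene length, and were most frequent at low abundance. Tested genes were put in 4 classes of equal size by mean abundance. That mean covers both groups, so a strong fall itself moves a gene to a lower class. In the class of lowest abundance, 23.2% were lower and 10.3% higher in msm. In the class of highest abundance, 7.33% were lower and 1.58% higher, so that lower genes outnumbered higher ones by 2.26 to 1 in the first and by 4.64 to 1 in the second. Of 4 such classes by coding length, the shortest had 13.7% lower and 5.03% higher genes, and the longest had 10.4% and 3.02%. The median coding length was 1083 bases for lower genes, 1011 for higher genes and 1122 for all tested genes.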

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

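The tests of library depth, of coverage, of the reads left in msm and of consecutive identifiers were chosen after the results were seen, and so were the coverage scan and the 256-fold set. The tests of scaling, of abundant genes and of other splits of the libraries were written down before their values were known.

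The deposited coverage column, which no comparison above uses, also differs between the groups. Among the 15268 genes with at least 200 reads in each library, 29 were covered at least 20 percentage points less in every msm library than in every wild-type library, and 2 the other way round. The highest count from another split of the libraries was 1, against 31 for both directions together in the real split. The other splits mix the groups on both sides, so genes that follow the groups could not count there. The comparison therefore does not test the 31. Of the 29 genes, 24 were not called by read count, 5 were called lower and none higher. Over all tested genes 12.5% were called lower and 4.64% higher. In the classes of highest and next-highest abundance, 7.33% and 6.89% were lower, and 1.58% and 2.23% higher. The shares among the 15268 genes examined were not computed, so whether these counts set the 29 apart was not tested. The minimum of 200 reads in each library also leaves out genes that were strongly lowered. An example singled out after its values were seen is Bra021727 (coding length 1770 bases). Reads covered 98.2% ± 0.29 of it in wild type and 9.81% ± 0.035 in msm (SD, n = 3 each), with 569 ± 15.9 and 443.7 ± 45.4 reads, and it was not called (log2 fold change -0.60).

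A lower read count in msm was weighed first. Covered length saturates with depth, so fewer reads alone would not lower it by a larger factor than the reads; in 21 of the 29 genes it fell by a larger factor in all 9 pairs of an msm and a wild-type library, which argues against it for those 21 (7 of them had more reads in every msm library). For the other 8 genes the median read ratio of msm over wild type was 0.575, which leaves it open. A missing or unmappable gene part in msm also stays open: with evenly spread reads it would change reads and covered length in proportion, and the log2 read ratio minus the log2 coverage ratio had a median of 0.595 (quartiles 0.317 and 0.802) but ran from -2.38 to 2.94 and lay below 0 in 6 of the 29 genes. The genes were chosen for low coverage, which raises this difference and so also favours the count of 21 in the test of a lower read count. That test is firm only for the 7 genes with more reads in every msm library. How reads lie along a gene is unknown here.

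The excess of lower over higher genes was weighed against technical sources. The msm libraries were not shallower (ratio of mean totals 1.015). Without the 100 most abundant genes, 73.1% of called genes were lower with TMM scaling. TMM trims extreme genes when it scales, so leaving these out could hardly move its scaling and decides little. Under total counts the fit was not run without them, so reads taken by abundant genes stay open as a source. Over 3 other scalings the lowest share was 61.21%, under total counts, and leaving out each library there gave 59.92% to 62.18%. That range falls below the 60% set in advance as the bound against scaling, so the planned criterion was not met by more than the spread; the argument against scaling as the whole cause rests on a criterion adopted after these values were seen, that the share stays above the 50% scaling would need, and part of the excess may come from scaling. In the real grouping edgeR called 4992 genes, and 1 of the 10 splits of the 6 libraries (the real grouping) gave as many. The highest other split gave 0 (0 in DESeq2, and 436 at an unadjusted p below 0.05 in edgeR). Every other split mixes wild-type and msm libraries on both sides, so the group difference counts as spread there. These splits therefore cannot show how many calls would arise without a group difference. In addition, 10 splits cannot give a share under 0.05. Genotype stays open and untested, as do differences in which tissues or stages the buds held.

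Small numbers of reads remained in msm for genes at least 256-fold lower there. Over these 338 genes the msm libraries 1, 2 and 3 held 932, 834 and 1342 reads, or 0.65, 0.581 and 0.935 for each 1000 reads of the mean wild-type library. Wild-type reads assigned to msm libraries could give each gene the same share, and the genes lost most fully allow such a share of at most 0.0523%, 0.0611% and 0.0904%. Between 31.8% (msm 3) and 47.5% (msm 1) of the reads left lay above what that share gives. For the 974 genes at least 32-fold lower the values were 81.1% to 88.8%. The fold threshold itself caps the reads a gene can hold in msm, so these percentages follow the threshold and decide nothing, and transferred reads and a low level of real expression cannot be told apart here.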

How the results depend on the processing

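The 2 counts of called genes were recomputed under 23 alternative settings. The count of higher genes stayed within 1.5 times of 1351 in 18 and that of lower genes within 1.5 times of 3641 in 20, and lower genes outnumbered higher ones in all 23. Limma with a pseudocount of 5 RPKM called 418 higher and 1418 lower genes. Limma with a pseudocount of 1 RPKM called 1020 and 2447; beside it, limma on quantile-normalized RPKM gave 2213 lower genes and limma on RPKM scaled by the median ratio 700 higher genes. In edgeR, total count scaling gave 2030 higher genes, and the test against a 2-fold change 744 higher genes. With no fold threshold 7802 genes were higher and 8764 lower. That setting was run with TMM alone, so its direction under other scalings is not known. A larger pseudocount shrinks the folds of low genes and the thresholds act by construction. Scaling moves all folds together: under total counts in edgeR the median log2 fold change was 0.222, against 0.00499 with TMM. All 1351 higher calls stayed there, and all 3203 lower calls were among the 3641. RPKM is scaled to total counts too, and in limma with a pseudocount of 1 the median was 0.196, against -5.09e-05 with the median ratio. For the other differences the cause was not tested. DESeq2 called 1281 and 3625. With 1 library left out, 1206 to 1245 of the higher and 3526 to 3570 of the lower genes remained called, none of the called genes changed sign, and the totals were 1329 to 1424 and 3695 to 3838. Quantile normalization turned the sign of 7 called genes.

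Genes on in wild type alone numbered 287 at 5 RPKM and 315 with no read in msm, against 553; those on in msm alone numbered 10 at 5 RPKM and 34 with no read in wild type, against 47. Without msm replicate 3 the first count was 651. The number of its genes that reached 100 RPKM, 21 in the full set, was 31, 26 and 37 without msm replicates 1, 2 and 3. The share of reads in abundant genes and the number of detected genes kept their direction in all 9 alternatives each, but at 5 RPKM the second difference was -81.3 and not -942. Coverage gaps, a scan and settings chosen after the data were seen, numbered 10 to 41 against 29. SWEET9 lost its call in 1 of 23 alternatives, and the 4 identifiers in none. Wild type and msm share the replicate numbers 1 and 2, whose libraries did not deviate together (r = -0.0473 and 0.0368 across genes); a replicate block over those 4 libraries called 1308 and 3655 genes, and 1326 and 3665 without the block. The tests of gene lists and chromosomes were not run, because 1 of the 35421 identifiers matched a name and no positions were used here. Depth limits genes unread in a group, whose folds are bounds.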

Other observations

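Genes that changed in the same direction tended to have consecutive identifier numbers; this and its test were chosen after the data were seen. Among the genes lower in msm, pairs with consecutive numbers exceeded by 120 the mean of 336 (268 to 401) found when the calls were shuffled 10000 times among genes of like abundance. The permutation p was 0.0001, the smallest these shuffles can give, so like abundance of neighbours, as far as 10 classes of abundance capture it, does not account for the excess. Shuffling among all genes gave a like mean of 340, so most of the pairs are the number chance gives. Among the genes higher in msm there were 80 pairs, against a mean of 46.8 (27 to 77), with the same p. If consecutive numbers mark neighbours in the genome, which was not checked here, then adjacent copies of a gene expressed together are a candidate explanation, and reads shared between such copies are another; neither was tested. Genes are not independent replicates, and the p describes only these calls.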
